A study of Rattus norvegicus with 9 samples.

How the data were processed

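RNA of the left ventricle of WKY, SHR and oxymatrine-treated SHR (3 samples per group, 9 in all) had been extracted with Trizol and made into libraries from total RNA with the KAPA RNA HyperPrep kit for the BGISEQ-500 platform, per the labels' protocols. The submitters' processing notes name Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the rat genome build Rnor_6.0, without their order or settings. Per the file headers, the authors' deposited table gives FPKM for each gene and sample, which scales estimated reads by gene length and by the library's total. The same deposited table holds the authors' own log2 ratio and q-value for SHR over WKY and for treated over untreated SHR, which were used only for comparison and are named as theirs. The dose, the duration, the animals' age and the time of collection are not given in the sources used here.

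The table had 22864 gene rows with NCBI Gene IDs and symbols, 3570 of them without values, so 19294 were read. For 27 genes the symbol had been turned into a date; all 27 were restored through the Gene ID in a RefSeq gene table of assembly GRCr8, which held 20690 of the table's Gene IDs. That table was used for names and for which genes neighbour each other, and no coordinates are given because its build differs from the authors'. Columns were assigned to samples by their names. The 13 mitochondrially encoded genes of one list had no row.

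Read counts were not used here and depth is unknown. To see whether low values step by whole reads, 96 genes above 0 in 2 to 5 libraries were examined: of 190 ratios to a gene's lowest value, 16.3% lay within 0.1 of a whole number, where even spacing gives 20%, so no read steps were recovered. No interval for counting error can therefore be given, and precision rests on the spread between samples. RSEM divides reads between similar genes, so near-identical copies can trade reads.

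Genes with a mean FPKM over the 9 samples of at least 1 were tested, 12451 in all, on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3: one fit over the 3 groups with 6 residual degrees of freedom, moderated with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No count model was run, because FPKM are not counts. The 3 pairwise comparisons and the F test over the groups came from this fit. Of 38 gene lists fixed before the data were examined, 25 of pathways and 13 of cell types, those with at least 5 tested genes (32) were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists. Estimated correlations and fry, which asks whether a list's genes move one way on balance, were alternatives. The tests of these comparisons, their samples, the lists and the rule for named genes were fixed before the data were examined.

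Named genes were, for each comparison, those with the largest changes in each direction (up to 10) among called genes whose groups did not overlap, without unnamed loci, then 17 heart genes given whatever their result, and up to 4 members of a described list with the smallest p, with other members where a count needed them. Some of the largest were left out for length, and some genes that the rule takes are not reported here. Genes outside this rule, such as Ephx1, Gstt1, Rnf213, Myl7, Sln and several genes of the third comparison and of the overlap between comparisons, were named after their values were seen.

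The fit and the list test were tested on simulated data, with 200 of 12451 genes changed by known folds on the fitted scale. For SHR against WKY 86.6% of 1.5-fold, 98.5% of 2-fold and 100% of 4-fold changes were recovered, with 7 false calls; for treated against untreated SHR 79.1%, 100% and 97.0%, with 14; for treated SHR against WKY 91.0%, 97.0% and 98.5%, with 6. Genes in the simulation varied independently, and a list shifted by 0.3 was found with 0 of the other lists called. Chance values for shared SHR libraries came from 100 simulations.

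Alternatives were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, fits of only the groups compared, sample weights, no variance trend, the replicate number as a block, each sample left out in turn, and a log2 change of at least 1. Figures were drawn with matplotlib.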

Results

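Messenger RNA of the left ventricle was measured by RNA sequencing in 9 rat samples of 3 groups. The groups were Wistar Kyoto rats (WKY, the normotensive strain commonly set against the hypertensive one), spontaneously hypertensive rats (SHR, an inbred strain with inherited high blood pressure) and SHR given oxymatrine, a quinolizidine alkaloid of Sophora roots, with 3 samples each. The values analysed were FPKM per gene, and 12451 genes with a mean FPKM of at least 1 were tested. Read depth is unknown, because the table held no counts. The sum of FPKM lay between 587526 and 606633 in the 9 libraries, and between 12231 and 12514 genes reached an FPKM of 1. The 20 most abundant genes took 18.1% to 18.3% of the FPKM sum in SHR, 16.8% to 17.1% in WKY and 16.8% to 17.9% in treated SHR. Correlations of log2(FPKM + 1) across genes were 0.988 to 0.991 within groups, 0.973 to 0.980 between WKY and the other groups, and 0.986 to 0.990 between untreated and treated SHR. The first principal component, with 46.2% of the variance, parted WKY from both SHR groups. The labels do not say whether the replicates came from separate animals, so the p-values measure the spread between these samples. Values are given as mean FPKM ± SD with n = 3 per group, and changes as log2 differences on the log2(FPKM + 1) scale, which understates the change of low genes.

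The first comparison, SHR against WKY, asked how the ventricle of the hypertensive strain differs from that of the normotensive one. SHR ventricles held much less Cd36, the fatty acid transporter of the muscle cell membrane (NCBI Gene ID 29184), at 197 ± 4.68 FPKM against 866 ± 79.3 in WKY, a log2 change of −2.13 (SE 0.068, adjusted p = 1.51e-07). They held more Ephx2, the soluble epoxide hydrolase that breaks down epoxides of arachidonic acid (NCBI Gene ID 65030), at 40.1 ± 4.33 FPKM against 10.2 ± 0.89 (log2 change 1.88, adjusted p = 1.89e-06). Endog, which encodes a mitochondrial nuclease, was lower in SHR, with a log2 change of −1.71 (adjusted p = 4.88e-06). Cd36, Ephx2 and Endog all belong to a fixed list of genes reported to differ genetically between hypertensive and normotensive rat strains. Of its 12 tested genes 1 rose and 3 fell, also adjusted over the list alone, where 33.9% of all tested genes were called. Fry placed that list lower (adjusted p = 8.15e-05), and camera did not call it (adjusted p = 0.404, and 0.594 with an estimated correlation). Of 19 genes induced in hypertrophied heart muscle 8 rose and 2 fell, and 23 of 24 interferon response genes, 20 of 23 antigen presentation genes and 17 of 20 cell division genes fell. The camera calls of these 4 lists were lost with an estimated correlation (adjusted p = 0.327, 0.327, 0.327 and 0.416). Fry, the other alternative, called all 4 in the same directions (adjusted p = 0.0221, 0.00142, 0.00127 and 0.00644). In all, 4215 of 12451 genes passed an adjusted p of 0.05 in limma, of which 196 changed by at least 1 on the log2 scale.

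**Figure D1:**
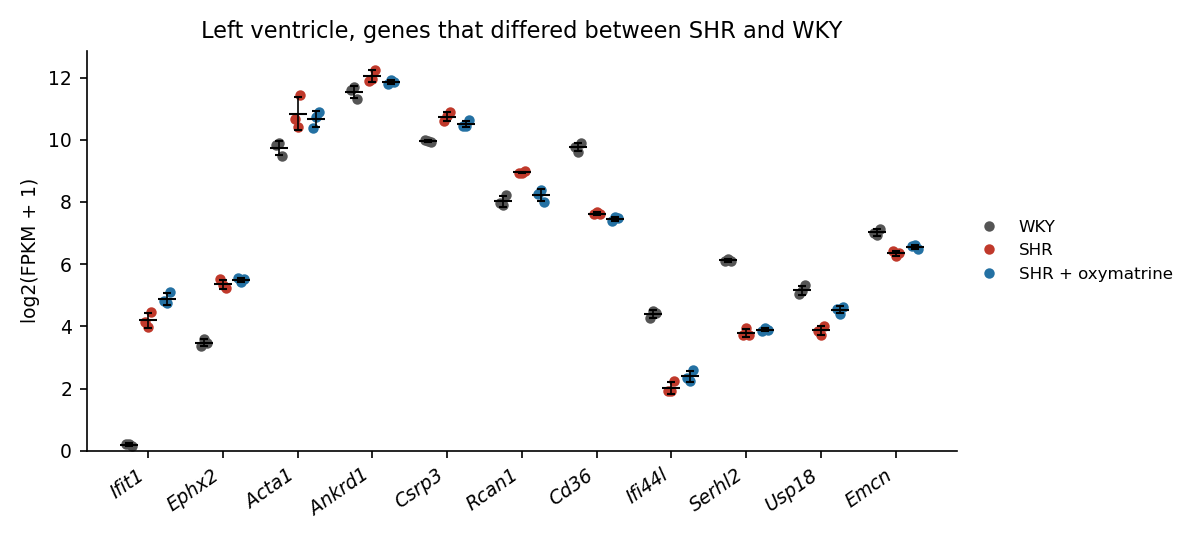
Level of 11 genes in each library as log2(FPKM + 1), with the mean (wide black bar) and SD (error bar) of the 3 libraries of WKY, untreated SHR and SHR given oxymatrine. Cd36 fell from a mean of 866 FPKM in WKY to 197 in SHR, and Ephx2 rose from 10.2 to 40.1.

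Among the genes with the largest changes, Ndufa10l1, a copy of a gene for a subunit of respiratory complex I, was near the floor in WKY (1.05 ± 0.51 FPKM) and at 86.3 ± 5.51 FPKM in SHR. The parent gene Ndufa10 had 263 FPKM in WKY and 235 in SHR, and the sum of both copies was 264 ± 10.2 in WKY and 321 ± 13.4 in SHR. Ifit1, an interferon-induced gene, had 0.147 ± 0.0321 FPKM in WKY and 17.5 ± 3.2 in SHR, opposite to the rest of its family list. Ptgfr, the prostaglandin F receptor, rose by 2.80 on the log2 scale, Tcp11x2 by 2.79, Setd4 by 2.48 and Slc17a7, a vesicular glutamate transporter, by 2.42. In the other direction, the class I histocompatibility gene RT1-N2 changed by −2.90, the interferon-induced Ifi44l by −2.36, Serhl2 by −2.33 and Rims1, a presynaptic gene, by −2.05. Hba-a1, a copy of the alpha globin gene, had 11.6, 31.5 and 26.2 FPKM in the WKY libraries, and the histone gene Hist1h2bk had 6.66, 7.23 and 6.64. Both were listed at 0 in all 3 SHR libraries, while Hba1, the other alpha globin gene, ran from 1031 to 2524 FPKM over the 9 libraries. Ndufa10l1, Hba-a1, Hist1h2bk and the RT1 genes belong to families of similar genes between which estimated reads could be split, so the values of single copies are uncertain.

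Of 19 tested hypertrophy-induced genes, 8 rose, 2 fell and 9 did not pass the test, and adjusted over the list alone 10 rose and 3 fell. Acta1, the skeletal alpha actin that the stressed ventricle re-expresses, rose from 849 ± 127 to 1914 ± 740 FPKM (log2 change 1.12, adjusted p = 0.00698). Xirp2 rose by 1.07, Rcan1, a feedback inhibitor of calcineurin, by 0.92, Tnfrsf12a, the TWEAK receptor, by 0.86, Csrp3, the muscle LIM protein, by 0.77, and Ankrd1 by 0.50. The 2 others that rose were Xirp1 and Fhl2, by 0.54 and 0.44, and the 2 that fell were Nes and Myh7b, with log2 changes of −0.78 and −0.35. Fhl2 lost its call in 11 of 18 alternatives and Myh7b in 10, with adjusted p-values of up to 0.13 and 0.14. The natriuretic peptide genes did not pass the test. Nppa had 1987 ± 681 FPKM in WKY and 3058 ± 1842 in SHR (adjusted p = 0.581), with 970, 3754 and 4450 FPKM in the single SHR libraries. Without SHR replicate 1 its adjusted p was 0.0412, the lowest in a range up to 0.995 over 18 alternatives. Nppa is also an atrial gene, and the atrial myosin gene Myl7 had 9.33, 8.06 and 1.49 FPKM in the WKY libraries and 0.92 to 1.29 in SHR. Sln, another atrial marker, had 10.8, 19.99 and 0.29 FPKM in WKY and 0, 3.35 and 6.48 in SHR replicates 1 to 3. Of 9 tested atrial markers, Nppa among them, 2 were called higher and 3 lower (camera adjusted p = 0.464). Nppb had 486 ± 45.9 and 635 ± 69 FPKM (adjusted p = 0.115, and 0.0241 to 0.27 over the alternatives, lowest with only the groups compared, and 0.0295 without treated replicate 1). The camera test placed the list above other genes (median log2 change 0.41, adjusted p = 0.000205), and with an estimated correlation the adjusted p was 0.327.

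Of 22 adult contractile and calcium-handling genes, 11 rose and 1, Hrc, fell, against 11 and 2 adjusted over the list alone. Ryr2, the calcium release channel of the sarcoplasmic reticulum, rose by 0.70, Slc8a1, the sodium-calcium exchanger, by 0.50 and Jph2, which holds the membrane junction of the calcium release units, by 0.40. Myh6, the fast alpha myosin heavy chain, rose from 2261 ± 64.8 to 2922 ± 380 FPKM (adjusted p = 0.014), and lost its call narrowly without WKY replicate 1 (adjusted p = 0.0521) or SHR replicate 2 (0.0519), the highest over its alternatives, whose lowest was 0.00187. Myh7, the slow beta chain, had 2158 ± 142 FPKM in WKY and 1773 ± 192 in SHR (adjusted p = 0.0624, and 0.0431 to 0.219 over the alternatives, passing without treated replicate 2 and with only the groups compared). Atp2a2, the calcium pump of the sarcoplasmic reticulum, rose by 0.24 (adjusted p = 0.0442), a call lost in 10 of 18 alternatives with adjusted p-values of up to 0.152. Hrc lost its call in 5 of 18, among them median-of-ratios scaling (adjusted p = 0.143). The list had a camera adjusted p of 1.78e-05, and an adjusted p of 0.327 with an estimated correlation. Of 21 potassium and sodium channel genes, 8 rose and 3 fell over all genes, against 9 and 3 adjusted over the list alone. Kcne1, an accessory subunit of the slow delayed rectifier, rose by 1.93, Kcnk3 by 0.90 and the pacemaker channel gene Hcn2 by 0.80, and Kcnd3, of the transient outward current, changed by −0.68. The channel list had a camera adjusted p of 0.00389, and an adjusted p of 0.327 with an estimated correlation.

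Of 35 tested genes of fatty acid uptake and oxidation, 16 rose and 2, Cd36 and the carnitine transporter Slc22a5, fell, and adjusted over the list alone 22 rose and 3 fell. Slc22a5 lost its call in 9 of 18 alternatives, with adjusted p-values of up to 0.266. Acadm, the medium-chain acyl-CoA dehydrogenase, rose by 0.44 and Acsl1 by 0.41. Cpt1b, the mitochondrial entry step, had 229 ± 2.96 FPKM in WKY and 253 ± 7.86 in SHR (adjusted p = 0.0635, and 0.0154 to 0.163 over the alternatives, lowest with median-of-ratios scaling and below the threshold also without treated replicate 1 or 3). Pdk4, which holds back pyruvate oxidation, had 44.2 ± 20.9 and 77 ± 24.8 FPKM (adjusted p = 0.068, and 0.0111 to 0.209 over the alternatives, lowest without WKY replicate 3). The camera adjusted p of this list was 2.4e-07, and 0.327 was the adjusted p with an estimated correlation. Of 28 glucose uptake and glycolysis genes, 13 rose and 4 fell, with 14 and 4 adjusted over the list alone. Eno1 rose by 1.65, Pfkl by 0.67 and the glucose transporter Slc2a1 by 0.47, whereas Eno3, Pfkfb3, Pgam2 and Gapdh fell (camera adjusted p = 8.57e-05, adjusted p = 0.327 with an estimated correlation). Of these 4, only Eno3 was called lower with median-of-ratios scaling, and it was not without WKY replicate 3 (adjusted p = 0.059). In the citric acid cycle, 7 of 18 genes rose and none fell, with 7 rising and 1 falling adjusted over the list alone. Ogdh rose by 0.80 and Idh3a by 0.51, and the list's camera adjusted p was 0.00389 (adjusted p = 0.597 with an estimated correlation, and 0.064 by camera with quantile normalization).

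Of the 24 interferon response genes, 23 fell and only Ifit1 rose, with the same counts adjusted over the list alone. The median log2 change was −0.91. Usp18, which curbs interferon receptor signalling, changed by −1.29, Ifi44 by −1.19 and Ifit2 by −1.01 (adjusted p = 6.67e-06). Of 23 antigen presentation genes, 20 fell and 1, RT1-A1, rose, also when adjusted over the list alone, with log2 changes of −1.37 for RT1-CE5, −0.99 for RT1-S3 and 1.21 for RT1-A1. Camera adjusted p-values were 1.19e-10 for the interferon list and 7.53e-07 for the antigen presentation list, and the adjusted p was 0.327 for both with an estimated correlation. Macrophage and monocyte markers had a median log2 change of 0.10, and 0 of 17 passed the limma test. Their camera adjusted p was 0.056, and it was below the threshold in 7 of 20 alternatives (0.00564 to 0.874). Lymphocyte markers had a median of −0.24, with 0 of 7 rising and 2 falling, also adjusted over the list alone, and a camera adjusted p of 0.87. The 2 were Nkg7, a granule gene of natural killer and cytotoxic T cells (−0.49, adjusted p = 0.0344), and the perforin gene Prf1 (−0.43, adjusted p = 0.0411), which lost their calls in 8 and 9 of 17 alternatives (adjusted p of up to 0.11 and 0.13), both other scalings among them. Cell division genes fell in 17 of 20 cases (19 adjusted over the list alone) and none rose, among them Tpx2 with −0.94, Mcm6 with −0.71 and the replication clamp Pcna with −0.36 (camera adjusted p = 9.12e-05, adjusted p = 0.416 with an estimated correlation). Endothelial markers fell in 8 of 12 cases over all genes and adjusted over the list alone, with Emcn at −0.68, Egfl7 at −0.66 and Pecam1 at −0.47 (camera adjusted p = 0.0034, adjusted p = 0.416 with an estimated correlation). Under the median-of-ratios scaling 6 of the 12 fell.

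The list of fibrosis genes was not called. Of 43 extracellular matrix and fibrosis genes, 1 rose and 11 fell, with the same counts adjusted over the list alone, and the list's camera adjusted p was 0.582. The counts were 3 and 6 with median-of-ratios scaling and 2 and 7 with quantile normalization. The collagen genes Col1a1 (55.2 ± 7.83 FPKM in WKY, 51.9 ± 10.2 in SHR, adjusted p = 0.704) and Col3a1 (239 ± 17 and 180 ± 46.1, adjusted p = 0.112) did not pass, nor did Postn (8.52 ± 1.55 and 8.83 ± 4.93, adjusted p = 0.927), Timp1 (16.6 ± 2.37 and 26.6 ± 10.5, adjusted p = 0.178) or Ace (7.44 ± 2.15 and 6.42 ± 1.61, adjusted p = 0.537). Agt, the angiotensin precursor gene, stayed below the filter, with 0.31 to 0.68 FPKM in the 9 libraries.

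Over all genes, 1343 were called higher and 2872 lower in SHR, 31.9% higher, and the median change of all genes was −0.084. With median-of-ratios scaling the split was 2033 higher and 1789 lower, 53.2% higher, and with quantile normalization 1881 and 1812. The authors' deposited table gave a q under 0.05 to 3009 genes, 1718 higher and 1291 lower. Of the 2852 among them that were tested here, 2430 were also called here, all with the same sign. Of 32 lists tested 13 were called, all of them lost with an estimated correlation, and another split of these 6 samples gave 17. Fry called 14 of the 32. The called lists not described above were heat shock genes (7 of 18 rose and 2 fell, 9 and 2 adjusted over the list alone, camera adjusted p = 0.0034, adjusted p = 0.327 with an estimated correlation), branched-chain amino acid breakdown genes (5 of 22 rose and none fell, also adjusted over the list alone, 0.0081 and 0.451) and arachidonic acid and eicosanoid genes (5 of 25 rose and 3 fell, also adjusted over the list alone, 0.0271 and 0.416). With median-of-ratios scaling 9 of the 22 branched-chain genes rose. All 3 of these calls were lost with quantile normalization (adjusted p = 0.0764, 0.0682 and 0.0595). The branched-chain call was also lost by fry (0.0773), and the arachidonic acid call by fry (0.0608), with median-of-ratios scaling (0.0674), at a mean FPKM of at least 5 (0.0723) and without WKY replicate 1 (0.0767).

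The second comparison, treated against untreated SHR, asked how the ventricle of SHR given oxymatrine differs from that of untreated SHR. The largest differences were in genes of the circadian clock. Dbp, a clock output transcription factor (NCBI Gene ID 24309), rose from 16.4 ± 0.924 to 77.1 ± 14.7 FPKM (log2 change 2.15, SE 0.19, adjusted p = 0.00298). Ciart and Per3, repressors of the clock, rose from 1.06 ± 0.201 to 7.88 ± 1.25 and from 3.34 ± 0.344 to 9.67 ± 0.573 FPKM, and Arntl, the activator also called Bmal1 (NCBI Gene ID 29657), fell from 18.7 ± 0.658 to 5.85 ± 0.87 FPKM (log2 change −1.53, adjusted p = 0.000588). Of 24 interferon response genes 3 rose, none of them with either other scaling, and the list's camera call was lost with an estimated correlation (adjusted p = 0.337). Rcan1 and Cdkn1a, which were called higher in SHR than in WKY, were lower in treated than in untreated SHR. In all, 30 of 12451 genes passed an adjusted p of 0.05 in limma, 19 higher and 11 lower.

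**Figure D2:**
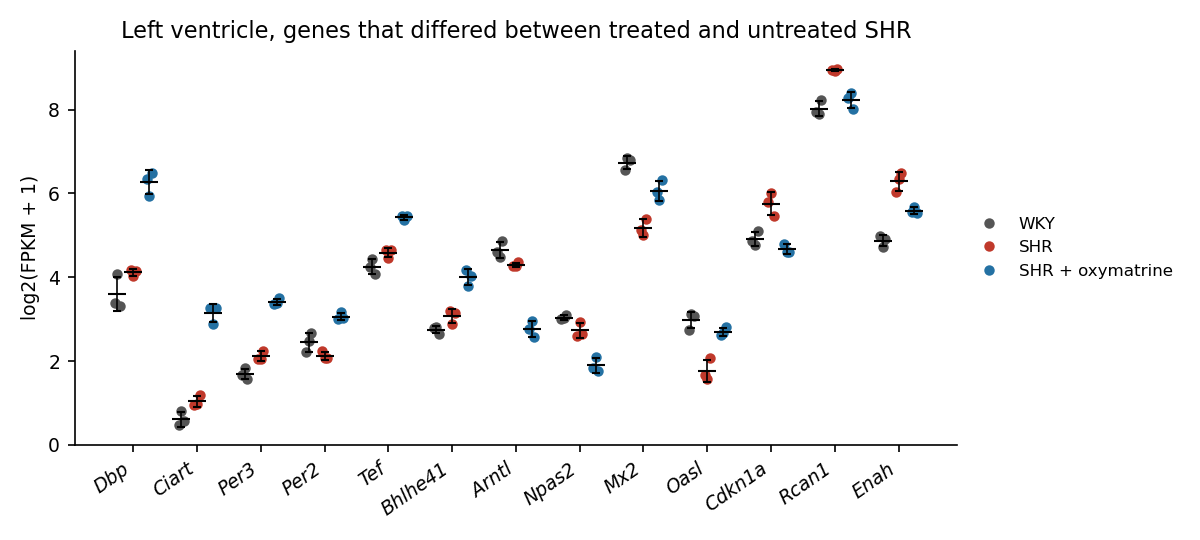
Level of 13 genes in each library as log2(FPKM + 1), with the mean (wide black bar) and SD (error bar) of the 3 libraries per group. Dbp stood at 77.1 FPKM in treated SHR against 16.4 in untreated SHR, Arntl at 5.85 against 18.7, and Rcan1 at 300 against 493.

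Of 17 tested clock genes, 7 rose, 2 fell and 8 did not pass, and adjusted over the list alone 10 rose and 4 fell. Besides Dbp, Ciart and Per3, those that rose were Per2 (0.94), Bhlhe41 (0.93), Tef (0.84) and Bhlhe40 (0.74), and those that fell were Arntl and Npas2 (−0.83), a partner of Arntl. Npas2 passed in 9 of 18 alternatives, Bhlhe40 in 10 and Per2 in 11, with adjusted p-values of up to 0.137, 0.137 and 0.101. The list had a median log2 change of 0.74, a camera adjusted p of 0.00236 and a fry adjusted p of 0.00012, the only list that fry called in this comparison. With an estimated correlation the adjusted p was 0.308. In untreated SHR against WKY, 6 of the same 17 genes were higher and 2 lower (8 and 4 adjusted over the list alone), with 0.43 for Per3 and −0.35 for Arntl. That list's camera adjusted p was 0.0987 (adjusted p = 0.327 with an estimated correlation), but 0.0483 by fry and, by camera, 0.0411 without WKY replicate 2, the lowest over the alternatives. With median-of-ratios scaling 8 were higher and none lower there, and the camera adjusted p was 0.235.

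All 24 interferon response genes had estimates above 0 in treated SHR, with a median log2 change of 0.40. Of these 24, 3 passed over all genes, Mx2 (35.4 ± 5.24 to 66.6 ± 11.6 FPKM, log2 change 0.89), Usp18 (0.67) and Ifit2 (0.42), and 17 rose adjusted over the list alone. These 3 calls were lost with either other scaling, where none of the 24 genes passed over all genes and the list's median was 0.36 and 0.35. Oasl, an interferon-induced gene outside the list, rose by 0.93, a call also lost with median-of-ratios scaling (0.0657) and quantile normalization (0.0662) and kept in 4 of 17 alternatives (adjusted p of up to 0.166). Of 23 antigen presentation genes none passed over all genes and 13 rose adjusted over the list alone. RT1-S3 (log2 change 0.35) had an adjusted p of 0.0693, and RT1-Ba (0.83) one of 0.142. Camera adjusted p-values were 1.55e-17 and 1.46e-08, but 0.337 and 0.379 were the adjusted p-values with an estimated correlation. Macrophage and monocyte markers had a median log2 change of 0.34, none passed, and their camera adjusted p was 0.776. Without treated replicate 3, which stood apart from the other libraries on the third principal component (20.5 against −10.8 to 3.25), it was 8.54e-05, in a range of 8.54e-05 to 0.957 over the alternatives. Lymphocyte markers had a median of 0.34 and estimates above 0 in 7 of 7, with none passing and 1, Nkg7 (0.53, adjusted p = 0.231 over all genes), rising adjusted over the list alone (camera adjusted p = 0.0424, adjusted p = 0.684 with an estimated correlation). Inflammation genes had a median of 0.17, with 25 of 29 estimates above 0 and none passing, also adjusted over the list alone (camera adjusted p = 0.0438, adjusted p = 0.772 with an estimated correlation). Both camera calls were lost in leave-outs, the lymphocyte list's without SHR replicate 2 (0.111) or 3 (0.161) or treated replicate 1 (0.0927) or 2 (0.151), and the inflammation list's without SHR replicate 1 (0.114), 2 (0.081) or 3 (0.17) or treated replicate 1 (0.0881) or 2 (0.275).

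**Figure D3:**
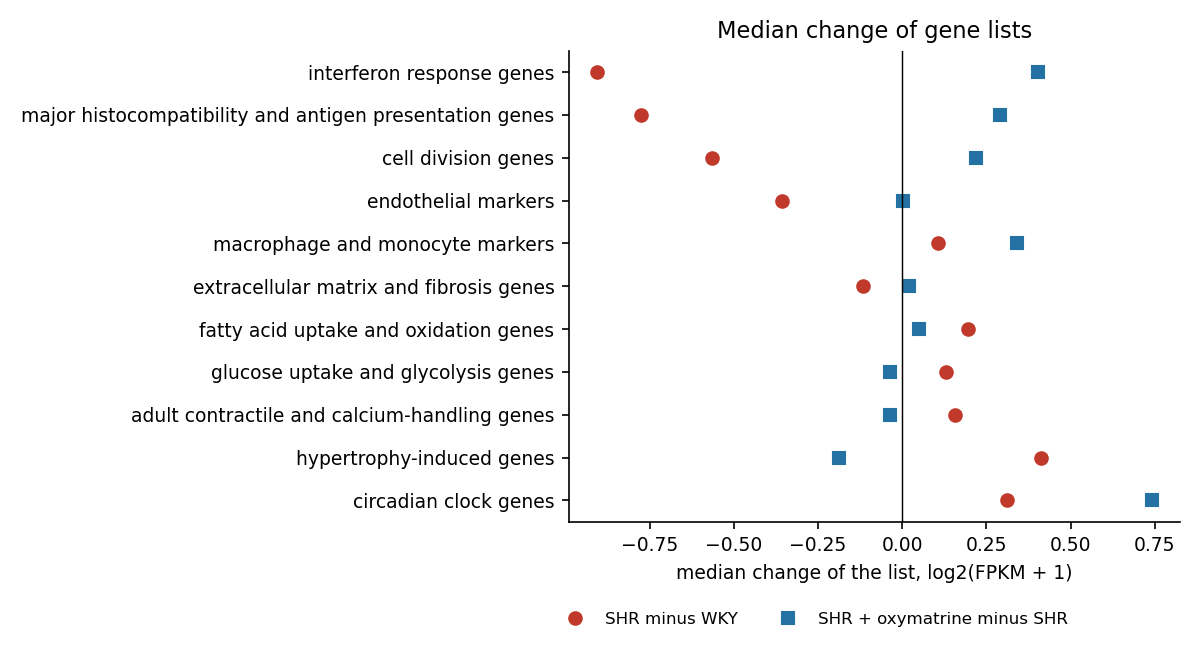
Median log2 change of the tested members of 11 gene lists, for SHR minus WKY (circles) and treated minus untreated SHR (squares). The interferon list stood at −0.91 and 0.40, the hypertrophy-induced list at 0.41 and −0.19, and the clock list at 0.31 and 0.74.

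Among hypertrophy-induced genes, 1 of 19 fell, Rcan1, from 493 ± 9.74 to 300 ± 39.4 FPKM (log2 change −0.72, adjusted p = 0.0324), and none rose. Rcan1 passed in 8 of 18 alternatives, with adjusted p-values of up to 0.14. Adjusted over the list alone 3 fell and 1 rose. Tnfrsf12a had 31.5 ± 4.19 FPKM without and 18.7 ± 3.06 with oxymatrine (adjusted p = 0.0693, and 0.0372 to 0.222 over the alternatives, passing with either other scaling and a mean FPKM of at least 5). Nppa (3058 ± 1842 and 1359 ± 497 FPKM, adjusted p = 0.512), Nppb (635 ± 69 and 461 ± 123, adjusted p = 0.324), Acta1 (1914 ± 740 and 1651 ± 287, adjusted p = 0.841) and Ankrd1 (4227 ± 578 and 3694 ± 154, adjusted p = 0.571) did not pass. The list had a median change of −0.19 and a camera adjusted p of 3.53e-06, with an adjusted p of 0.337 with an estimated correlation. Myh6, Myh7 and Atp2a2 had log2 changes of 0.04, −0.13 and 0.03 with adjusted p-values of 0.913, 0.69 and 0.934. None of the 22 adult contractile and calcium-handling genes passed, also adjusted over the list alone, and 8 estimates lay above 0. Camera placed that list lower (median −0.035, adjusted p = 0.00213), but the adjusted p was 0.673 with an estimated correlation, and by camera 0.716 with quantile normalization, 0.0997 without SHR replicate 2 and 0.222 without treated replicate 2.

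Other genes called lower included Cdkn1a, a cell cycle inhibitor (53.7 ± 9.98 to 24.5 ± 2.03 FPKM, log2 change −1.09), Ypel2 (−0.85), Enah, an actin regulator (−0.69), Uck2 (−0.53), the glycogen-targeting Ppp1r3c (−0.43) and Asph (−0.34). Rgs16, which shortens G protein signals, rose by 0.87, Ephx1, the microsomal epoxide hydrolase, by 0.65 and the glutathione transferase Gstt1 by 0.59. Genes of fuel use and fibrosis that did not pass were Cd36, with a log2 change of −0.17 (adjusted p = 0.362), Ephx2 with 0.15 (0.539), Cpt1b with 0.05 (0.753), Pdk4 with −0.43 (0.643), Col1a1 with 0.16 (0.776), Col3a1 with 0.20 (0.738), Postn with 0.74 (0.461), Timp1 with 0.25 (0.809) and Ace with −0.13 (0.861), with adjusted p in parentheses. Camera placed the 28 glucose uptake and glycolysis genes lower (median −0.04, adjusted p = 0.0161, adjusted p = 0.684 with an estimated correlation), with 10 estimates above 0 and none passing, also adjusted over the list alone. That call was lost with quantile normalization (0.72), without SHR replicate 1 (0.214) or 2 (0.0997) and without treated replicate 2 (0.589). No member of the fatty acid list (35 tested), the citric acid cycle list (18) or the extracellular matrix list (43) passed, and their camera adjusted p-values were 0.426, 0.316 and 0.25. The fatty acid list was called with quantile normalization (0.0109, in a range up to 0.844), the citric acid cycle list without SHR replicate 3 (0.0106) or treated replicate 3 (0.00402, in a range up to 0.983), and the matrix list without SHR replicate 2 (0.00191) or treated replicate 2 (0.000362, in a range up to 0.971).

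Markers of other cells and further lists were also called by camera, with no genes passing over all genes. Schwann cell and nerve markers had a median log2 change of 0.62, with 0 of 6 passing and 5 rising adjusted over the list alone (camera adjusted p = 8.19e-05, adjusted p = 0.379 with an estimated correlation). Cell division genes had a median of 0.22 and heat shock genes one of −0.07, with 0 of 20 and 0 of 18 passing, also adjusted over the list alone (camera adjusted p = 0.00281 and 0.000199, adjusted p = 0.715 and 0.337 with an estimated correlation). Atrial markers had a median of −0.16, with 0 of 9 passing and 1 falling adjusted over the list alone (camera adjusted p = 0.0173, adjusted p = 0.673 with an estimated correlation). Fibroblast markers had a median of −0.09 and 6 of 12 estimates above 0, with none passing, also adjusted over the list alone (camera adjusted p = 0.0411, adjusted p = 0.772 with an estimated correlation). The 71 nuclear-encoded respiratory chain genes had a median of −0.01 and the 77 ribosomal protein genes one of 0.00204, above 0 although camera placed them lower, and none of either passed, also adjusted over the list alone (camera adjusted p = 0.0027 and 0.0411, adjusted p = 0.772 and 0.844 with an estimated correlation). With quantile normalization the direction of both turned. Leaving out SHR replicate 1 ended the calls of fibroblast markers (0.136), respiratory chain (0.514) and ribosomal genes (0.152), SHR replicate 2 those of cell division genes (0.153) and atrial markers (0.348), and SHR replicate 3 those of fibroblast markers (0.263) and ribosomal genes (0.35). So did treated replicate 1 for fibroblast markers (0.078), treated replicate 2 for respiratory chain (0.984) and ribosomal genes (0.263), and treated replicate 3 for fibroblast markers (0.42) and ribosomal genes (0.387), and the median-of-ratios and quantile scalings for fibroblast (0.0847 and 0.243) and atrial markers (0.0772 and 0.172). Of 32 lists, 15 were called and none with an estimated correlation, and another split of these 6 samples also gave 15.

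The count of 30 genes moved when single samples were left out. WKY samples do not enter the difference between treated and untreated SHR, and act on this count only through the spread estimate shared by the 3 groups. Each leave-out also lowers the residual degrees of freedom, so the counts do not single out particular samples. The count was 33 without WKY replicate 3, 24 without WKY replicate 2, 6 without treated replicate 1, 7 without SHR replicate 2, 13 without WKY replicate 1 or treated replicate 3, 16 without treated replicate 2, 18 without SHR replicate 3 and 19 without SHR replicate 1. Dbp, Arntl, Per3, Ypel2 and Ephx1 passed in 18 of 18 alternatives and Ciart in 17 of 17, whereas Cdkn1a passed in 11, Mx2, Usp18, Ifit2, Rgs16 and Asph in 6, Enah in 5 and Gstt1 in 2 of 17. The higher share was 63.3% of calls, but 10 of 23 calls (43.5%) with median-of-ratios scaling and 11 of 21 (52.4%) with quantile normalization. At an unadjusted p of 0.05, 1512 genes passed. The authors' deposited table gave a q under 0.05 to 163 genes for this comparison, 76 higher and 87 lower. Of the 154 among them that were tested here, only 28 were also called here, all with the same sign. Those 28 were among the 30 genes called here.

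The third comparison set treated SHR against WKY, to see how far treated ventricles remained from those of the normotensive strain. Cd36 was at 175 ± 7.92 FPKM against 866 ± 79.3 (log2 change −2.30, adjusted p = 9.16e-08), Ephx2 at 44.3 ± 2.19 against 10.2 ± 0.89 (2.02), and Ndufa10l1 at 86.2 ± 4.78 against 1.05 ± 0.51 (5.44). Ifit1 was higher by 4.69 and Tcp11x2 by 2.86, and RT1-N2 was lower, with −2.70. Clock genes also differed, with 2.67 for Dbp, 2.53 for Ciart, 1.72 for Per3 and −1.88 for Arntl. Altogether 3095 genes passed, 1274 higher and 1821 lower, and 150 of them changed by at least 1.

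By list, 20 of 24 interferon response genes remained lower than in WKY and Ifit1 higher, with a median of −0.57 (22 lower adjusted over the list alone), including Mx2 at −0.67 and Usp18 at −0.62. Of the fatty acid genes 22 of 35 were higher and 2 lower (25 and 3 adjusted over the list alone). Of the clock genes 10 of 17 were higher and 5 lower, with the same counts adjusted over the list alone. Camera adjusted p-values for these lists were 7.77e-08, 1.54e-08 and 0.00133, and with an estimated correlation the adjusted p was 0.448, 0.448 and 0.259. Ryr2 was higher by 0.62, Myh6 by 0.40 and Acta1 by 0.96 (adjusted p = 0.0188), and Myh7 was lower, with −0.41 (adjusted p = 0.0203). Acta1 did not pass without WKY replicate 3 (adjusted p = 0.063), treated replicate 2 (0.0507) or treated replicate 3 (0.0614), and Myh7 not with quantile normalization (0.0686), without WKY replicate 1 (0.0757) or without treated replicate 2 (0.0584), in ranges from 0.00335 and 0.0148. Rcan1 (0.20, adjusted p = 0.189), Cdkn1a (−0.24, adjusted p = 0.209) and Ankrd1 (0.32, adjusted p = 0.0759, and 0.0454 to 0.222 over the alternatives, passing without WKY replicate 2 or SHR replicate 3) did not differ past the threshold, and Enah was still higher by 0.72 (adjusted p = 0.00172). Of 32 lists, 15 were called and none held with an estimated correlation, and another split of these samples gave 17. Fry called 15 of the 32. The split of calls, 41.2% higher, was 54.5% with median-of-ratios scaling, and the count was 1893 without WKY replicate 1 and 2024 without treated replicate 1.

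The 3 groups together differed in 3743 genes by limma's F test. Between the first and the second comparison, 20 genes were called in both, 15 of them in opposite directions. Those lower in SHR and higher with oxymatrine were Mx2, Oasl, Usp18, Ifit2, Rnf213, RT1-T24-3, Gprc5b and Rgs16. Cdkn1a, Rcan1, Enah, Uck2, Ppp1r3c, Asph and an unnamed locus were higher in SHR and lower with oxymatrine. Of the calls with oxymatrine, that of Gprc5b was made in 16 of 18 alternatives, of Uck2 in 9, of Ppp1r3c in 8, of RT1-T24-3 in 6 and of Rnf213 in 4 of 18 (adjusted p of up to 0.0532, 0.14, 0.153, 0.14 and 0.166). The 5 that moved one way in both were the clock genes Ciart, Per3, Bhlhe41, Tef and Arntl, of which only Per3 was called between SHR and WKY in all 18 alternatives (Arntl lost that call in 10 of 18, Ciart in 10 of 17, Bhlhe41 in 8 and Tef in 5 of 18). Without treated replicate 1 just 1 gene was called in both comparisons, and with quantile normalization 13. Independent lists of these sizes would share 5.57 genes in opposite directions and 4.59 in the same direction, and simulated libraries with the strain effect and no treatment effect shared 0.11 genes on average. The simulated value is low by construction, since without a treatment effect few genes are called in the second comparison, so it is no chance value for the overlap of 30 such calls. Nor are 5.57 and 4.59 chance values, since both comparisons use the same SHR libraries, which alone favours opposite signs.

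**Figure D4:**
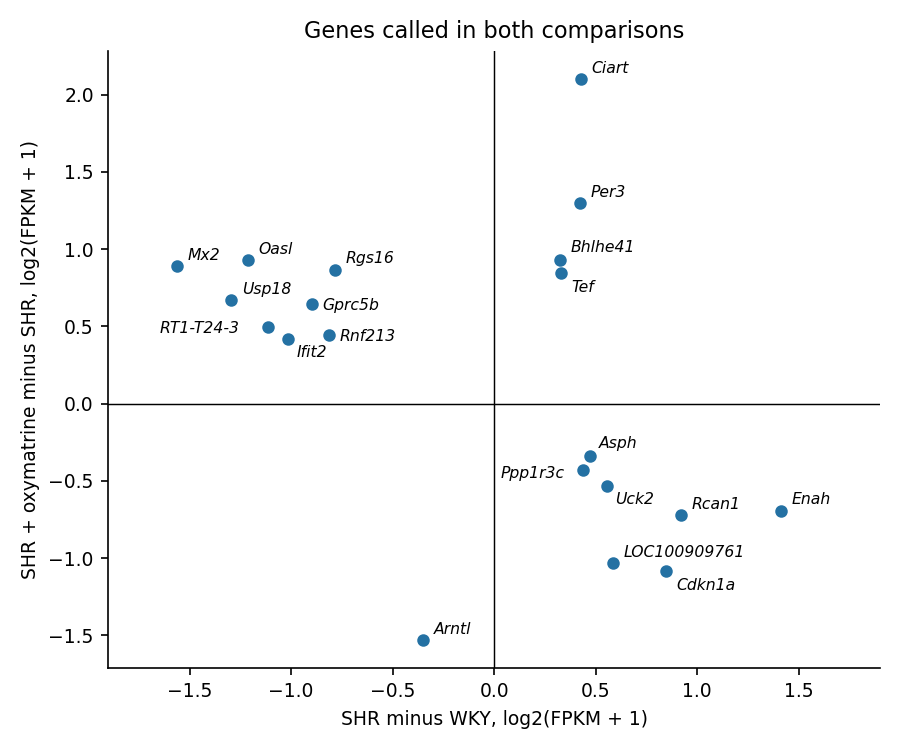
Log2 changes of the 20 genes called in both comparisons, SHR minus WKY on the horizontal axis and treated minus untreated SHR on the vertical axis, each point 1 gene. The 15 genes in the upper left and lower right moved in opposite directions, and 5 clock genes moved one way in both.

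Of the 4215 genes called between SHR and WKY, 78.2% had an estimate of opposite sign between treated and untreated SHR. Both comparisons use the same SHR libraries, which alone gives opposite signs. Simulated libraries with no effect at all gave 79.7% among as many top genes, and with the strain effect kept and no treatment effect the share was 58.5% (56.3% to 60.3% over 100 simulations). The strain effect kept there was the observed difference of means, which already holds sampling noise. Its size is therefore overstated, and 58.5% may lie too low as a value without treatment effect. With the strain calls made on 2 SHR libraries and the treatment change measured against the other one, the share was 67.1%, 70.4% and 63.5%. The covariance of the changes was −0.0240, and −0.00929 in the simulation without treatment effect. Genes in these simulations varied independently, whereas the estimated correlation within the interferon list was 0.601. Variation shared by many genes widens such ranges, so the simulated ranges cannot decide whether treatment reversed strain differences.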

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

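All alternatives were planned before the data were examined. The count for SHR against WKY stayed within 1.5 times of 4215 (2882 to 4218 without 1 sample) except for the stricter 196 genes with a log2 change of at least 1, and that for treated SHR against WKY was 1893 to 3043 without 1 sample and 150 at that size. Genes differing among the groups were 2262 to 3568 without 1 sample. For treated against untreated SHR the 30 genes became 12 without the filter, 19 with only the groups compared, 17 without the variance trend, 7 at a log2 change of at least 1, and 6 to 33 without 1 sample. The 20 genes called in both comparisons became 4 without the filter, 13 with quantile normalization, 9 without the trend, and 1 to 21 without 1 sample. The cause was not tested, apart from the fewer samples and the stricter size. The opposite-direction share of 78.2% was 75.3% with quantile normalization and 72.4% to 81.9% without 1 sample. With the replicate number as a block, counts were 3550, 14 and 2473 for the 3 comparisons, 6 genes were called in both and 2850 differed among the groups; same-numbered samples did not deviate together (correlations −0.109 to 0.0276 over 9 pairs, with 1 of 9 samples closest to its own number), so the numbers were not taken to pair samples. List counts of 13, 15 and 15 became 0, 0 and 0 with an estimated correlation and 14, 1 and 15 with fry, and were 12 to 16, 11 to 16 and 13 to 16 without 1 sample.

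Of the named genes' values, 1534 for SHR against WKY kept call and direction, 109 lost the call and 9 gained it. For treated against untreated SHR 616 kept it, 194 lost it and 3 gained it, and for treated SHR against WKY 369, 6 and 2. Signs turned only for genes that did not pass. Without 1 sample, log2 changes between SHR and WKY ran from −0.31 to 0.018 for Ace, −0.21 to 0.067 for Col1a1 and −0.44 to 0.20 for Postn, which was at 0.029 with median-of-ratios scaling and 0.058 with quantile normalization. Between treated and untreated SHR they ran from −0.31 to 0.0055 for Ace, −0.37 to 0.14 for Acta1, −0.012 to 0.28 for Col1a1, −0.023 to 0.35 for Col3a1, −0.073 to 0.11 for Myh6 and −0.046 to 0.096 for Atp2a2, and with median-of-ratios scaling Myh6 was at −0.0096 and Atp2a2 at −0.020. List directions turned, not past the threshold, for ribosomal protein (adjusted p = 0.461), respiratory chain (0.829) and citric acid cycle genes (0.387) with quantile normalization, for citric acid cycle (0.983) and matrix genes (0.971) by fry, all between treated and untreated SHR. They also turned without 1 sample, where adjusted p-values ran from 0.00402 to 0.925 for citric acid cycle genes, 0.000362 to 0.762 for matrix genes, 0.0612 to 0.758 for fatty acid genes and 8.54e-05 to 0.865 for macrophage markers in that comparison, and 0.226 to 0.907 for matrix genes and 0.615 to 0.994 for lymphocyte markers between SHR and WKY; the latter also turned with only the groups compared (0.952) and with sample weights (0.987). Depth is unknown, so what low genes can show was not bounded.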

Other observations

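The tests of collection time, of sequence variants and of immune cells, and the splits of 6 samples, were chosen after the results they bear on were seen. The others were written before their own test values were seen. Those on glucocorticoid exposure and on a single SHR library still address clock and interferon patterns that had already been found. Outside the groups described, 3 of 20 tested receptor genes of pressure hormones were higher in SHR than in WKY and 7 lower, also adjusted over the list alone, where 33.9% of all tested genes were called; with median-of-ratios scaling 3 were higher and 5 lower. The natriuretic peptide receptor genes Npr1 and Npr2 changed by −0.52 and −0.45 and Adra1d by −0.63; the list was not called by camera (adjusted p = 0.582, and 0.882 with an estimated correlation), and fry placed it lower (adjusted p = 0.0255). Of 32 antioxidant genes 7 rose and 5 fell (9 and 7 adjusted over the list alone, and 11 and 3 over all genes with median-of-ratios scaling), with Srxn1 at 0.93, Hmox1 at 0.97 and the NADPH oxidase gene Nox4 at −1.12 (camera adjusted p = 0.0612, adjusted p = 0.336 with an estimated correlation, and by camera 0.0295 without SHR replicate 3, 0.0339 without WKY replicate 2 and 0.0359 at a mean FPKM of at least 5). Mesothelial markers were uneven between libraries: Msln, a marker of the heart's outer lining, had 10 FPKM in SHR replicate 3, 7.18 in treated replicate 2 and 2.63 in SHR replicate 2, and 0 to 1.33 in the other 6 libraries.

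Clock genes differed between treated and untreated SHR. If all tissue of a group had been taken at another time of day, genes that peak with the activator Arntl and genes that peak with Dbp would move apart, and 17 of 17 tested clock genes moved so with the repressors Cry1 and Nfil3 placed on the side of Arntl, or 15 of 17 with these 2 placed with the other repressors; the directions were assigned after some of the values had been seen. Higher glucocorticoid exposure can also set tissue clocks. The 14 tested target genes changed by −0.0357 on average (95% bootstrap interval −0.192 to 0.131, under the bound of 0.3), with 5 above 0 and none called. These genes gave no sign of higher exposure at collection. The interval resamples genes and not samples, so it cannot exclude such exposure, and an earlier exposure was not tested. An effect of oxymatrine that shifts the phase of the clock would predict the same directions as another collection time. Collection time is confounded with the group, so both stay open. Other effects of oxymatrine on the clock were not tested.

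The interferon list had a median log2 change of −0.907 between SHR and WKY, where 23 of 24 genes fell. Between treated and untreated SHR it was 0.402 (0.316 to 0.465 without 1 library), where 3 of 24 passed and none with either other scaling. Both camera calls of the list were lost with an estimated correlation (adjusted p = 0.327 and 0.337). The fry adjusted p was 0.00142 for the first of these comparisons and 0.073 for the second. A single SHR library did not carry the first change, as the median was still −0.849 in the leave-out nearest 0, and sequence variants of the strain against the reference were argued against for the second, since both groups share a strain. Fewer macrophages in SHR than in WKY were argued against too: at a pseudocount of 0.1, 17 markers had a mean change of 0.168 (SD between libraries 0.167), whereas the interferon list had −0.736. Fewer lymphocytes there stay open, with −0.283 over 7 low markers (SD 0.27). More macrophages in treated than in untreated SHR also stay open (0.152, SD 0.418), where the interferon list had 0.46. For more lymphocytes in treated SHR the rule was met, and they stay open too. The 7 low markers rose by 0.523 (SD 0.262), past the bound of 0.23 by more than the SD, though none passed over all genes. Strain, oxymatrine and unrecorded exposure of the animals stay open as untested explanations, and sequence variants stay open for the difference between strains.

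Genes called between SHR and WKY lay beside each other more often than chance. In the gene order of GRCr8, 950 adjacent pairs were called in one direction, against 798 on average and 889 at most in 10000 permutations. Reads shared between neighbouring copies were argued against as the whole cause, since without pairs of one family or unnamed loci the ratio to the permuted mean was still 1.15. Pairs 10 genes apart had a ratio of 1.03, with 805 pairs against 785 on average and 871 at most in the permutations. No excess beyond the permuted range was thus seen at that distance. A block of 10 genes holds no such pair and a slightly longer one only a few, so blocks of about that size stay open. Only pairs called in one direction were counted, so blocks whose genes differ in both directions stay open. Shorter blocks, regulation shared by neighbours and reads running from one gene into the next were not tested.

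Other splits of the samples were counted for each number of calls. For SHR against WKY the real split gave 4215 genes and the highest other 1, for treated against untreated SHR 30 and 2, and for treated SHR against WKY 3095 and 2; in each, 1 of 10 splits gave as many genes, and 10 splits are too few for a share under 0.05. For the lists the same holds for the number of splits, with 13 called and 17 in the highest other split for SHR against WKY (4 of 10 splits gave as many), 15 and 15 for treated against untreated SHR (2 of 10), and 15 and 17 for treated SHR against WKY (2 of 10). For genes differing among the 3 groups the real grouping gave 3743 and the highest other 2953. The real one was the only 1 of 100 groupings as large, the lowest share that 100 groupings can give. That argues against an arbitrary division of these samples, but it does not say which groups differ. For genes called in both comparisons the counts were 20, 2 and 1 of 100, but no other assignment called more than 7 genes between treated and untreated SHR, so an overlap of 20 was out of reach and chance was not tested.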
